A study of Mus musculus with 5 samples.

How the data were processed

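The series has 5 samples of sorted striatal neuronal nuclei from 8-week-old C57BL/6 mice: 4 chromatin immunoprecipitations (H3K4me3, H3K27me3, H3K27ac and Pol II) and 1 input. Each antibody has 1 library. Groups were taken from the antibody given in the labels. The input enters only through the authors' region lists, which were made over input, and no signal track or read of any library was used here. Read depth is therefore not known from these files, and how depth differs between the 4 libraries could change how many regions each list holds.

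Per the submitters' processing notes, Bowtie 0.12.7, MACS 1.4 and build mm9 were used, with no role or order given. The deposited files list regions by position, each paired with a RefSeq transcript and a gene symbol and with a score given by the authors for the region over input. The scale of the score, fold or log, and the tool that gave it are not given in the sources used here. No listed score was below 2, no region was narrower than 2500 bp, and region bounds lay on a grid of 100 bp. The names of the deposited lists state a window of 3 kb on each side of the transcription start site. Regions wider than that window are listed whole. A wide H3K27me3 region was therefore taken to be listed for each gene whose start it reaches, a rule that the sources used here do not state. Each list belongs to 1 library, per the labels. The score was used only to rank or filter regions within 1 list.

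Transcript accessions were matched to a gene table of GRCm38.p6, used for names, biotypes and chromosomes only, and between 97.4% and 98.0% of accessions matched per list. The remaining transcripts were matched by symbol. No gene was found for 52 symbols and 0.341% of lines, which were left out. The background was the 21031 protein-coding genes with a curated RefSeq transcript. A gene carried a mark when at least 1 region was listed for it. A gene with no region, such as Foxp1 or Csf1r, counts as unmarked, although the files give no list of the transcripts that were searched, so the shares of lists with such genes rest on that choice. Its width is that of its widest region and its score that of its highest-scoring region. For 12 H3K4me3 and 33 H3K27me3 regions that were listed with different scores, the higher was kept. Positions are mm9, counted from 1.

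With 1 library per antibody there is no test across samples, and no p-value was computed. Overlaps of marks are given as counts, as the ratio to the number expected from independent lists of the same sizes, and as the place of the count among 10000 random lists drawn with seed 7. Log2 ratios were computed after adding 0.5 to the observed and expected counts. Gene lists were compared with random lists of the same size, and called above or below when outside percentiles 2.5 to 97.5. Shares carry exact (Clopper-Pearson) 95% intervals. Random lists were not matched on CpG content or gene length, since no genome of build mm9 was used here, and they take genes as independent although neighbours share regions. Differences between H3K4me3 genes with and without H3K27me3 were also averaged within 5 bins of H3K4me3 width. Positions were intersected with bedtools 2.31.1, counting 1 bp or more as shared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

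The gene lists, the main comparisons and the other settings were chosen before the data were examined, except where stated. The closing sections also hold later comparisons. Lists written by symbol covered medium spiny neurons, their pathways, other neurons, glia and vessels, developmental factors, signalling, cell death, the cell cycle, immediate early genes, housekeeping, Polycomb members, other tissues and germline. A total of 622 of 623 list symbols matched. Families were taken by symbol pattern, which also takes in genes of associated proteins such as Grid2ip, and histone genes, whose symbols have changed, through older symbols. Genes were named by rule: those of the 10 highest-scoring regions per mark, of the 10 widest H3K4me3 and H3K27me3 regions, and the 10 genes per overlap with the highest score of the second mark. Of each list, up to 6 members with the highest score of the mark discussed and up to 6 without it were named, or all members of a list of 16 or fewer. Names outside the rule, such as exceptions to a count, were chosen after their values were seen. Some genes that the rule would name are not reported.

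The statistics were tested on simulated data. The simulated genes were drawn independently, so the effect of neighbours that share regions was not covered. In 21031 simulated genes with no association, 5 of 100 simulated overlaps of H3K4me3 and H3K27me3 fell outside the central range, and all 100 did with a weight ratio of 0.8 or of 1.25. For H3K4me3 width over 14377 genes, 2 of 20 lists of 29 genes with no change were called, and a list of 29 with widths raised 1.5-fold was called in 20 of 20 simulations. A list of 9 was called in 2 of 20 with no change, in 11 of 20 at 1.5-fold and in 20 of 20 at 2.0-fold. A list of 29 genes with a true H3K4me3 share of 0.9 among 21031 genes was called in 84 of 100 simulations, and in 5 of 100 with the background share.

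The other settings were the upper 50% of each list by score, the same number of top regions from each list, autosomes only, genes sharing a region counted as 1 locus, and a background of genes with at least 1 mark. Regions sharing at least 1 bp or 0.5 of the narrower one, matching by older symbols, and other definitions of width were also tried. Leaving out olfactory and vomeronasal receptor genes was added after the data were seen. Noncoding genes were left out of the comparisons and are given at the end. Enhancers and other regions away from transcription start sites were not analysed here.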

Results

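Chromatin was profiled in neuronal nuclei of the striatum of 8-week-old C57BL/6 mice. The labels name them medium spiny neurons, the GABAergic projection neurons that make up most striatal neurons. The nuclei were sorted on NeuN, which marks neurons in general, and chromatin immunoprecipitation with sequencing was done with 4 antibodies. H3K4me3 marks promoters, H3K27me3 is laid down by the Polycomb repressive complex, H3K27ac marks active promoters and enhancers, and RNA polymerase II (Pol II) transcribes the genes. There was 1 library per antibody and 1 input library, so the data have no replicates, and every interval given here covers counting error only. The authors' region lists name regions near transcription start sites of annotated transcripts, each with the authors' own score over input. Read depth is not known from these files.

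The first question was which promoters carried each mark. The H3K4me3 list held 13142 regions and reached 14377 of 21031 protein-coding genes (68.4%, exact 95% interval 67.7 to 69.0%). H3K27ac reached 10822 genes (51.5%) in 9781 regions, H3K27me3 reached 8929 genes (42.5%) in 8219 regions, and Pol II reached 8773 genes (41.7%) in 7799 regions. H3K27me3 regions were the widest, with a median of 12400 bp against 6400 bp for H3K4me3, 5300 bp for H3K27ac and 4900 bp for Pol II. Regions wider than 20 kb made up 33.9% of the H3K27me3 list and 2.43% of the H3K4me3 list. No region of any of the 4 antibodies was listed for 2787 coding genes (13.3%), and these files do not show whether each of them was covered. With the upper 50% of each list by score, the counts of coding genes were 7774 for H3K4me3, 5265 for H3K27me3, 5492 for H3K27ac and 4450 for Pol II.

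The highest-scoring H3K27me3 regions lay over developmental transcription factor genes. Nkx2-4 led the list with a score of 16.2 over a region on chromosome 2 (mm9, 146902801 to 146943000). Next came the forkhead genes Foxc1, Foxe1, Foxc2 with Foxl1, and Foxf1, then by Wt1, Gata4, Tcfap2c, the Hoxc cluster and Foxl2. Wt1 is a regulator of kidney development and Gata4 of heart and gut development. The widest H3K27me3 region covered 937 kb of chromosome 1 with Prox1, Smyd2, Ptpn14 and Cenpf, and others of the 10 widest lay over Tshz2 (455 kb), Ebf3 (453 kb), Irx3, Irx5 and Tshz3.

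The other antibodies led with a different group of genes. Cpeb2, which encodes a cytoplasmic polyadenylation element binding protein, had the highest score of both H3K27ac (18.8) and Pol II (9.24), and the fourth of H3K4me3 (16.3). Arid1b, a subunit of the BAF chromatin remodelling complex, was second for H3K27ac with 17.7. Rbfox3, which encodes the NeuN antigen used for sorting, was also among the first 10 with 16.6. The striatal genes Pde10a and Bcl11b were also among the 10 highest H3K27ac regions, with scores of 15.9 and 15.5. The leading Pol II regions included those of Malat1, Ngef, Mir124a-1, Sp3, Vgf and Jund. H3K4me3 was led by Cdk13 (18.0), Kcnn2 (16.9), a calcium-activated potassium channel gene, and Sh3rf3 (16.4).

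The next question was how the marks combined at genes. Genes with H3K27ac or Pol II almost always had H3K4me3. Of the 10822 genes with H3K27ac, 10803 also had H3K4me3 (99.8%), against 7398 expected from independent lists, an observed over expected ratio of 1.46. For Pol II the number was 8753 of 8773 genes (99.8%), against 5997 expected, also a ratio of 1.46. H3K27ac and Pol II shared 8566 genes, 1.90 times the expected 4514. The largest class of genes carried H3K4me3, H3K27ac and Pol II without H3K27me3, with 7317 genes (34.8%). Among them were Cpeb2, Arid1b, Ngef, Phip, Sp3, Spred1, Egr1 and Junb. The upper 50% of each list kept 5031 genes with H3K4me3 and H3K27ac and 3955 with H3K4me3 and Pol II.

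H3K4me3 and H3K27me3, the pair of marks that defines bivalent promoters, occurred together at 5091 genes. These were 57.0% of genes with H3K27me3 and 35.4% of genes with H3K4me3. The number was below the 6104 expected from independent lists, with a ratio of 0.834, and below all 10000 random lists, the lowest of which shared 5977 genes. Among genes with both marks, the highest H3K27me3 scores were at Nkx2-4 (16.2), Foxc1 (14.9), Foxe1 (14.6), Foxc2, Foxl1, Mthfsd, Foxf1, Wt1, Them7 and Fdft1. At Foxc1 a 16.2 kb H3K4me3 region lay with a 141 kb H3K27me3 region, and at Wt1 the widths were 19.0 kb and 235 kb. In 2823 genes (13.4%) these were the only marks listed, and in 1248 (5.93%) all 4 antibodies had a region. The count depends on how many regions are kept: 787 genes had both marks in the upper 50% of each list, and 1747 when each list was limited to the same number of top regions.

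H3K27ac and H3K27me3, which modify the same lysine, were listed together at 2181 genes against 4595 expected, a ratio of 0.475. H3K27me3 and Pol II shared 1344 genes against 3725 expected, a ratio of 0.361. Among genes with both H3K27ac and H3K27me3, the highest H3K27me3 scores included genes that share a region with a developmental factor. Mthfsd shared the region of Foxc2 and Foxl1 with a score of 14.5, Fdft1, a gene of cholesterol synthesis, shared that of Gata4, Faim shared that of Foxl2, and Aatf that of Lhx1. Bub3, Ier3ip1, Etfa, Pfdn4, Ap5b1 and Cox6b1 were also among the 10, with H3K27ac regions of ordinary width, for example 5.0 kb at Bub3 and 5.1 kb at Cox6b1. When regions had to share 0.5 of the narrower one, 621 genes remained, and 276 genes had both marks in the upper 50% of each list and 1325 in lists of the same length.

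Genes with H3K4me3 were then divided by H3K27me3, to ask whether H3K27me3 goes with fewer of the active marks, H3K27ac and Pol II. A Pol II region was listed at 26.4% (25.2 to 27.6%) of the 5091 genes with both H3K4me3 and H3K27me3. Among the 9286 genes with H3K4me3 and no H3K27me3 the share was 79.8% (79.0 to 80.6%), a difference of -53.4 points. For H3K27ac the shares were 42.7% (41.3 to 44.1%) and 92.9% (92.4 to 93.4%), a difference of -50.2 points. Both differences lay below all 10000 random reassignments of H3K27me3 among H3K4me3 genes, which did not go below -3.30 points. Within 5 bins of H3K4me3 width the mean differences were -40.0 points for Pol II and -42.0 points for H3K27ac, and each bin had the same sign. The bins did not match the genes on H3K4me3 score, whose median percentile was 28.5 with H3K27me3 and 66.3 without. In lists of the same length the overall differences were smaller, -30.8 points for Pol II and -27.7 points for H3K27ac. Of the 3838 genes with H3K27me3 and no H3K4me3, 2 had Pol II and 7 had H3K27ac. Genes are not independent of each other, since neighbours can share a region.

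**Figure D1:**
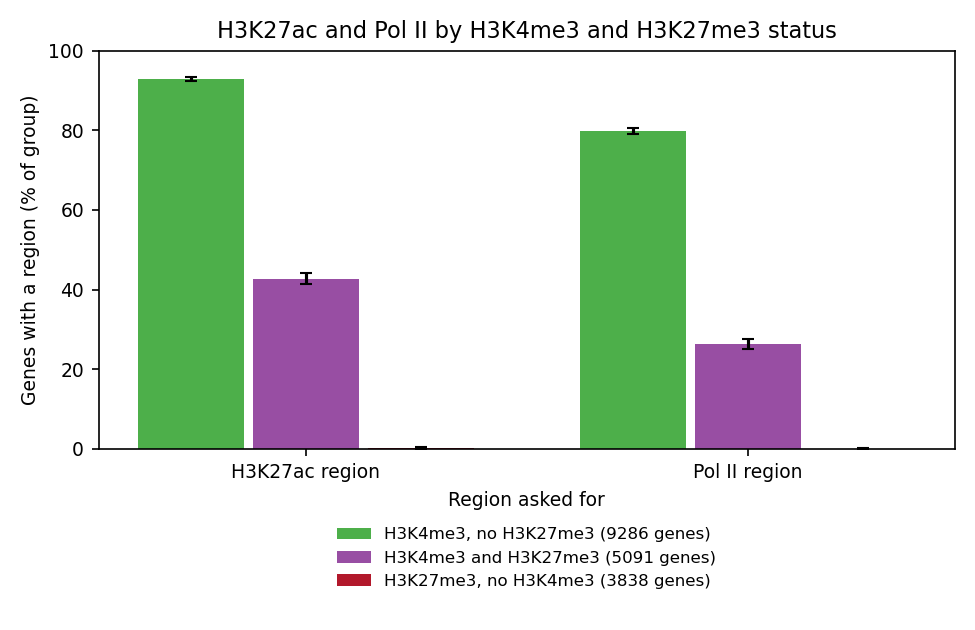
Percentage of genes with a H3K27ac region (left) and a Pol II region (right) in 3 groups of coding genes by H3K4me3 and H3K27me3, with exact 95% intervals as error bars. Pol II was listed at 79.8% of H3K4me3 genes without H3K27me3, at 26.4% of those with it, and at 2 of 3838 genes with H3K27me3 and no H3K4me3.

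The following comparisons take 37 gene lists, 23 written by gene symbol and 14 by symbol pattern, and ask which share of each list carried each mark. Of the 148 comparisons of a list with a mark, 111 lay outside the central 95% of random lists of the same size, and 59 lay beyond all 10000 random lists. By chance 7.4 outside the central range would be expected if genes were independent. Neighbours share regions, as in the Hox clusters, and some genes, such as En1 and Lmx1a, belong to several lists. The 111 are therefore not separate findings.

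Genes shared by the medium spiny neuron types carried H3K4me3, H3K27ac and Pol II over wide regions. Of 29 such genes, 28 had H3K4me3, 26 had H3K27ac (89.7%, 72.6 to 97.8%) and 23 had Pol II (79.3%, 60.3 to 92.0%), against 19.8, 14.9 and 12.1 expected. In 18 of them H3K4me3, H3K27ac and Pol II were listed without H3K27me3. Pde10a, the striatal phosphodiesterase, had a 109.7 kb H3K4me3 region, the third widest of that list, and a 193 kb Pol II region. Bcl11b, which encodes the transcription factor Ctip2, had H3K4me3 over 73.9 kb, H3K27ac over 65.3 kb and Pol II over 48.1 kb. At Adcy5, the main striatal adenylyl cyclase gene, Pol II extended over 105 kb. Ppp1r1b, which encodes Darpp-32, shared a 51.5 kb H3K4me3 region with the neighbouring Neurod2. Rasd2, Gad1, Arpp21 and Slc32a1, the vesicular GABA transporter gene, also carried H3K4me3, H3K27ac and Pol II, Slc32a1 with a 6.2 kb H3K27me3 region besides. H3K27me3 was listed at 10 of the 29 genes, within the range of random lists, with the highest score at Gsx2 (10.04), a progenitor factor, followed by Dlx1 and Dlx2 (7.40), Six3 and Zfp503. Gsx2 and Dlx1 had neither H3K27ac nor Pol II, whereas Dlx5 and Dlx6 had both and no H3K27me3. No region was listed for Foxp1 in the files used here.

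Markers of the direct and indirect pathways differed from these shared genes in H3K27me3. All 9 direct-pathway genes had H3K4me3 and H3K27me3, 8 had H3K27ac and 6 had Pol II. Of the 7 indirect-pathway genes all had H3K4me3, H3K27ac and Pol II, and 6 had H3K27me3. The expected H3K27me3 counts were 3.82 and 2.97, and both observed counts lay above the central range of random lists. The dopamine receptor gene Drd1 carried all 4 marks, with a 38.7 kb H3K27me3 region on chromosome 13 (mm9, 54127301 to 54166000) around an 11.4 kb H3K27ac region. Drd2 did so as well, with 54.2 kb of H3K27me3 and 9.6 kb of H3K27ac. Adora2a, the adenosine receptor gene of indirect-pathway neurons, had a 94.5 kb H3K27me3 region with 21.3 kb of H3K27ac. Tac1, Chrm4, Isl1, Ebf1 and Slc35d3 of the direct pathway, and Penk, Gpr6, Sp9 and Ptprm of the indirect pathway, also carried all 4 marks. Pdyn, the prodynorphin gene, had H3K4me3 and H3K27me3 without H3K27ac or Pol II, and Gpr52 was the 1 pathway gene without H3K27me3. Sfxn1 lies in the same H3K27me3 region as Drd1.

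**Figure D2:**
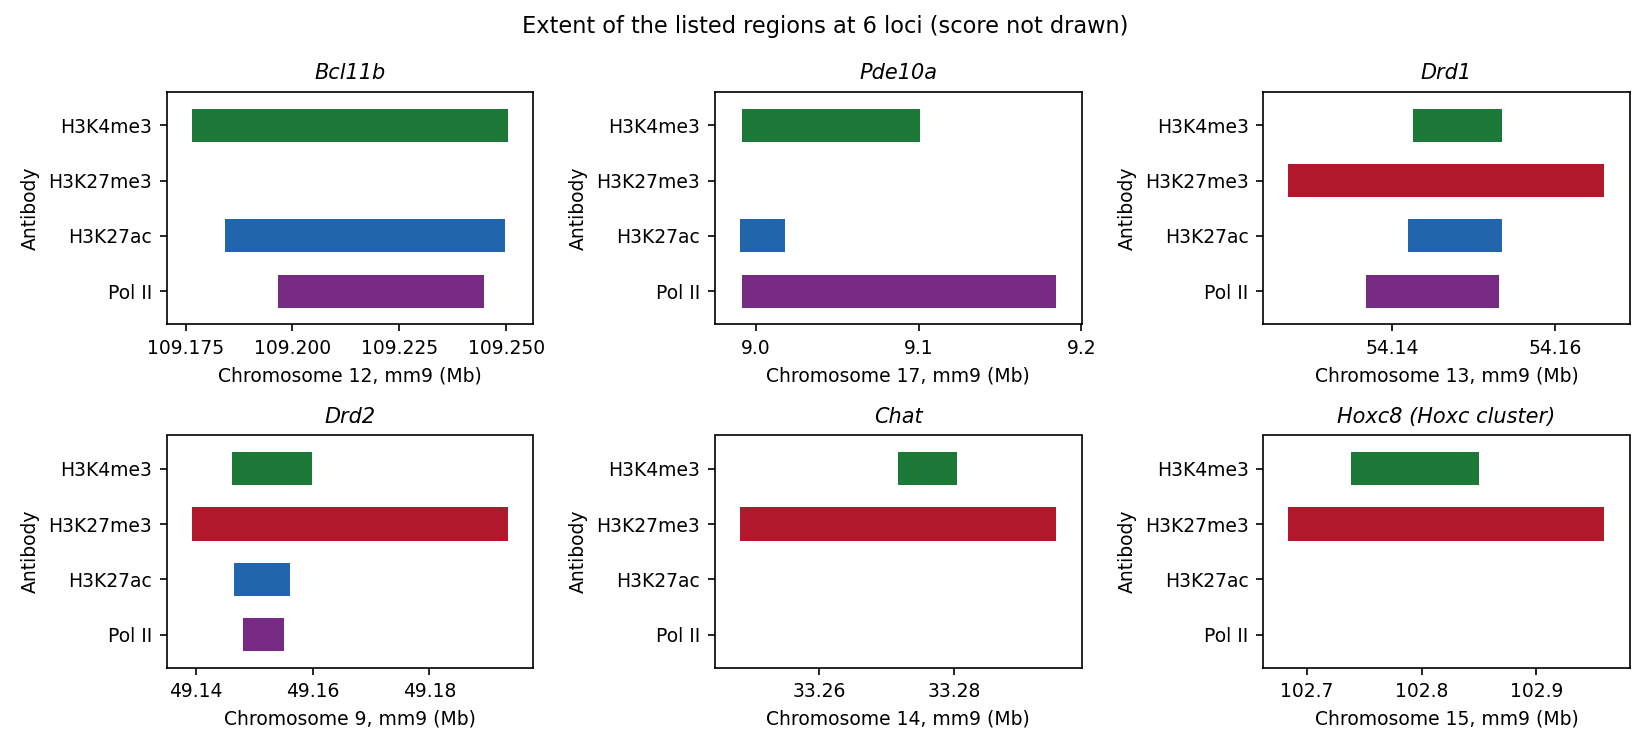
Highest-scoring listed region of each antibody (rows) for the named gene at 6 loci, along the chromosome (mm9, Mb). Bars show position and width, not score. Other listed regions in the window, such as those of neighbouring genes, are not drawn. H3K27me3 is missing at Bcl11b and Pde10a, surrounds H3K4me3, H3K27ac and Pol II at Drd1 and Drd2, and occurs with H3K4me3 alone at Chat and in the Hoxc cluster.

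Genes of other neuron types carried H3K27me3, and those of interneurons and monoaminergic neurons carried few active marks. H3K27me3 was listed at 14 of 15 striatal interneuron genes, at all 15 glutamatergic genes and at all 15 monoaminergic genes, against 6.37 expected in each. H3K27ac was listed at 1, 4 and 1 of them against 7.72 expected, and Pol II at 1, 7 and 2 against 6.26 expected. The interneuron and monoaminergic counts lay below the central range of random lists, and the glutamatergic counts of both lay within it. At Chat and Slc18a3, the cholinergic genes, a 46.8 kb H3K27me3 region scored 12.8, and Sst, the somatostatin gene, lay in a 185 kb region. Npy, Pvalb, Calb2, Lhx6, Nkx2-1, Htr3a and Th also had H3K27me3 without H3K27ac or Pol II. Cck had H3K27ac, Lhx8 had Pol II, and Nos1 had no region listed in the files used here. Of the glutamatergic genes, Eomes (13.0), Neurog2 (12.03), Neurod2 (11.2) and Bhlhe22 (10.9) had the highest H3K27me3 scores, and the genes with H3K27ac included Cux2, Slc17a7 and Neurod2, the last through the 28.9 kb region of the neighbouring Ppp1r1b. The dopamine and serotonin transporter genes Slc6a3 and Slc6a4 had H3K4me3 and H3K27me3 alone. Of the H3K4me3 counts of these 3 lists (11, 14 and 13 genes), only the glutamatergic one lay above the central range. In the upper 50% of the H3K4me3 regions the log2 ratios turned negative, to -3.60 and -2.01 for interneuron and monoaminergic genes, below the central range, and to -1.27 for glutamatergic genes, within it.

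Pan-neuronal genes had the opposite pattern. All 25 had H3K4me3 and H3K27ac, and 24 had Pol II against 10.4 expected. H3K27me3 was listed at 3 against 10.6 expected: Elavl4, where the widest of its regions was 63.1 kb, and Grin1 and Nefl with regions of 3.8 kb and 3.6 kb. Camk2a, Rbfox3, Gria2 and Snap25 had among the highest H3K4me3 scores of the list, between 11.6 and 12.1, with H3K27ac and Pol II.

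Markers of non-neuronal cells, which lack NeuN, had few active marks. Of 14 endothelial and mural genes, including Cldn5, Flt1, Kdr and Pdgfrb, all had H3K27me3 and none had H3K27ac or Pol II, which allows a share of up to 23.2%. Of 16 microglial genes, 12 had H3K27me3, 1 had H3K27ac and none had Pol II. C1qa, C1qb and C1qc shared an 80.0 kb H3K27me3 region, and Csf1r, Aif1, P2ry12 and Ptprc had no region listed in the files used here. Of 16 oligodendrocyte genes, 12 had H3K27me3, 2 had H3K27ac and 3 had Pol II. Mbp and Cnp carried H3K27ac (scores of 7.01 and 3.43) and Pol II (2.24 and 2.22, near the lowest listed score of 2). Olig2 had a 103 kb H3K27me3 region scoring 11.4. Of 13 astrocyte genes, 11 had H3K27me3, 4 had H3K27ac (Aldoc, Slc1a2, Slc4a4 and Sox9) and 2 had Pol II. The H3K27ac scores of Aldoc (2.17) and Sox9 (2.01) were near the lowest listed score, and those of Slc1a2 (3.67) and Slc4a4 (5.74) were higher. The astrocyte H3K27ac and Pol II counts and the oligodendrocyte Pol II count lay within the range of random lists.

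Developmental transcription factor genes outside the striatal programme carried H3K27me3 almost without exception. All 39 Hox genes and all 49 regional neural factors had H3K4me3 and H3K27me3, and 53 of 54 non-neural factors had H3K27me3, 47 of them with H3K4me3. H3K27ac was listed at none of the Hox genes, at 2 regional factors (Pitx3 and Shox2) and at 1 non-neural factor (Runx2). The upper limit for the Hox genes, 9.03%, takes them as independent, although members of a cluster share regions. Evx2, Evx1, Sim1, Lhx1 and Pax2 had the highest H3K27me3 scores of the regional factors, from 12.7 to 13.9. Pol II was listed at no Hox gene, but at 18 regional factors, within the range of random lists, and at 11 non-neural factors against 22.5 expected. Among those with Pol II were Tal1, Tlx3, Gata2 and Sim1, and Tbx2, Alx4, Six2 and Msx1. In a comparison chosen after the result was seen, 27 of the 96 factors with H3K4me3 and H3K27me3 (28.1%) had Pol II without H3K27ac. Among other genes with both marks it was 67 of 4995 (1.34%). The contrast lies in H3K27ac, listed at 3.13% of these factors and 43.5% of the other genes, while Pol II was listed at 30.2% and 26.3%. H3K4me3 scores of these lists were low. In the upper 50% of the H3K4me3 regions their log2 observed over expected ratios turned to -4.90 for Hox, -2.41 for regional and -3.03 for non-neural factors, from 0.54, 0.54 and 0.34. By symbol family, H3K27me3 was listed at 30 of 44 Fox genes, 13 of 19 Sox genes and 12 of 13 T-box genes, all above the central range. The Fox genes with H3K27ac and no H3K27me3 included Foxo3 and Foxo1. The H3K4me3 log2 ratio of Fox genes (37 of 44) turned to -0.21, within the random range, in the upper 50% of the regions, and that of T-box genes (11 of 13, within that range) to -3.41, below it.

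Signalling genes were often marked by both H3K4me3 and H3K27me3. Of 50 Wnt, Bmp, Hedgehog and Fgf pathway genes, 49 had H3K4me3, 46 had H3K27me3 (92.0%, 80.8 to 97.8%), 16 had H3K27ac and 8 had Pol II. Gdf6, Gdf7, Ihh, Wnt8b and Bmp4 had the highest H3K27me3 scores among them, from 9.49 to 10.7. Ptch1, Wnt2 and Wnt4 had H3K27ac and no H3K27me3. All 26 cell death and cell cycle inhibitor genes had H3K4me3 and 16 had H3K27me3 against 11.04 expected. Trp73 had the highest H3K27me3 score, 10.6. Cdkn2a and Cdkn2b, the Ink4 inhibitor genes, shared a 56.3 kb H3K27me3 region scoring 10.2 and a 42.6 kb H3K4me3 region, without H3K27ac or Pol II. Bcl2l11, Cdkn1c and Pmaip1 had the same pair of marks alone, while Trp53, Hrk, Bbc3, Bax, Casp9 and Apaf1 had H3K27ac and Pol II and no H3K27me3. All 25 cell cycle genes had H3K4me3, whereas 12 had H3K27me3 against 10.6 expected, 10 had H3K27ac and 6 had Pol II, all 3 within the range of random lists. Ccnd1, with 25.3 kb, had the highest H3K27me3 score of that list, 8.96. The H3K4me3 excess was lost in the upper 50% of the regions, with log2 ratios of -0.20 for the signalling list and -0.0362 for the cell cycle list, both within the random range.

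Genes of constitutive and activity-dependent expression carried active marks. All 48 ribosomal protein genes had H3K4me3, H3K27ac and Pol II, as did 40 of 41 oxidative phosphorylation genes. H3K27me3 was listed at 6 and 8 of them against 20.4 and 17.4 expected. Of 32 Polycomb complex members, 29 had H3K27ac and 27 had Pol II, and 6 had H3K27me3, among them Pcgf1, Cbx8, Ezh1, Pcgf3 and Cbx2. Of 25 immediate early genes, 22 had H3K27ac and 23 had Pol II, against 12.9 and 10.4 expected. Jund, Egr1, Junb and Arc had Pol II scores between 7.07 and 7.27, within the highest of the Pol II list. Of the 3 genes without H3K27ac, Bdnf and Ier2 had H3K4me3 and H3K27me3 and no Pol II, and Nr4a2 had all but H3K27ac. The H3K27me3 region of Bdnf, the neurotrophin gene, was 67.6 kb wide with a score of 9.21.

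Ion channel and neurotransmitter receptor genes divided within families. All 27 genes with glutamate receptor symbols, which include the scaffold gene Grid2ip, had H3K4me3, and 21 had H3K27ac against 13.9 expected. Grik5, Gria2, Grin2a and Grin2b led in H3K27ac, while Grin2c, Grm6 and Grin2d had H3K4me3 and H3K27me3 alone. Of 26 calcium channel genes, 21 had H3K27ac, led by Cacna2d3 with a score of 15.2, and 20 had Pol II against 10.8 expected. Of 19 GABA-A receptor genes, 10 had H3K27ac and Pol II, including Gabra2, Gabrb2 and Gabra4, and 5 had H3K27me3. All 4 shares of this family lay within the range of random lists. Of 94 potassium channel genes, 54 had H3K27ac against 48.4 expected, led by Kcnj4, Kcnab1 and Kcna1. For H3K27me3 the count was 47 against 39.9 expected, and both counts lay within the range of random lists. The highest H3K27me3 scores were at Kcnc1 (10.99), Kcnj6 and Kcnj1. Of 57 clustered protocadherin genes all had H3K4me3, 35 had H3K27me3 and 5 had H3K27ac, among them Pcdhac2, Pcdhgc4 and Pcdhgc5. The protocadherin H3K4me3 log2 ratio turned from 0.54 to -2.62 in the upper 50% of the regions. Of 375 solute carrier genes, 187 had H3K27me3, above the central range, led by Slc6a5 (13.2), the glycine transporter gene, and Slc18a3.

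Genes of other tissues mostly had H3K27me3 alone or no region. Of 37 structural and enzyme genes of other organs, 29 had H3K27me3, 13 had H3K4me3 and 6 had H3K27ac, and Ins2 had the highest H3K27me3 score, 10.5. Of 53 keratin genes, 40 had H3K27me3 and 10 had H3K4me3. Of 20 germline genes, 13 had H3K27me3 and 4 had H3K4me3. H3K27me3 was listed at 835 of 1108 olfactory receptor genes (75.4%, 72.7 to 77.9%) and at 203 of 355 vomeronasal receptor genes (57.2%, 51.9 to 62.4%), and H3K27ac at none and at 3 of them. The H3K27me3 scores of these 1038 receptor genes were mostly low, with a median percentile of 38.8 within the H3K27me3 list. In the upper 50% of the H3K27me3 regions the log2 ratios were -0.65 for germline genes, within the random range, and -0.77 for vomeronasal receptor genes, below it, from 0.59 and 0.43. Of 395 zinc finger protein genes, 334 had H3K4me3, 286 had H3K27ac and 119 had H3K27me3 against 168 expected. Of 67 replication-dependent histone genes, 62 had H3K4me3 and 49 had Pol II, and 4 had H3K27me3 against 28.4 expected. Their H3K27ac count of 46 turned from a log2 ratio of 0.41 to -1.08 in the upper 50% of the regions.

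**Figure D3:**
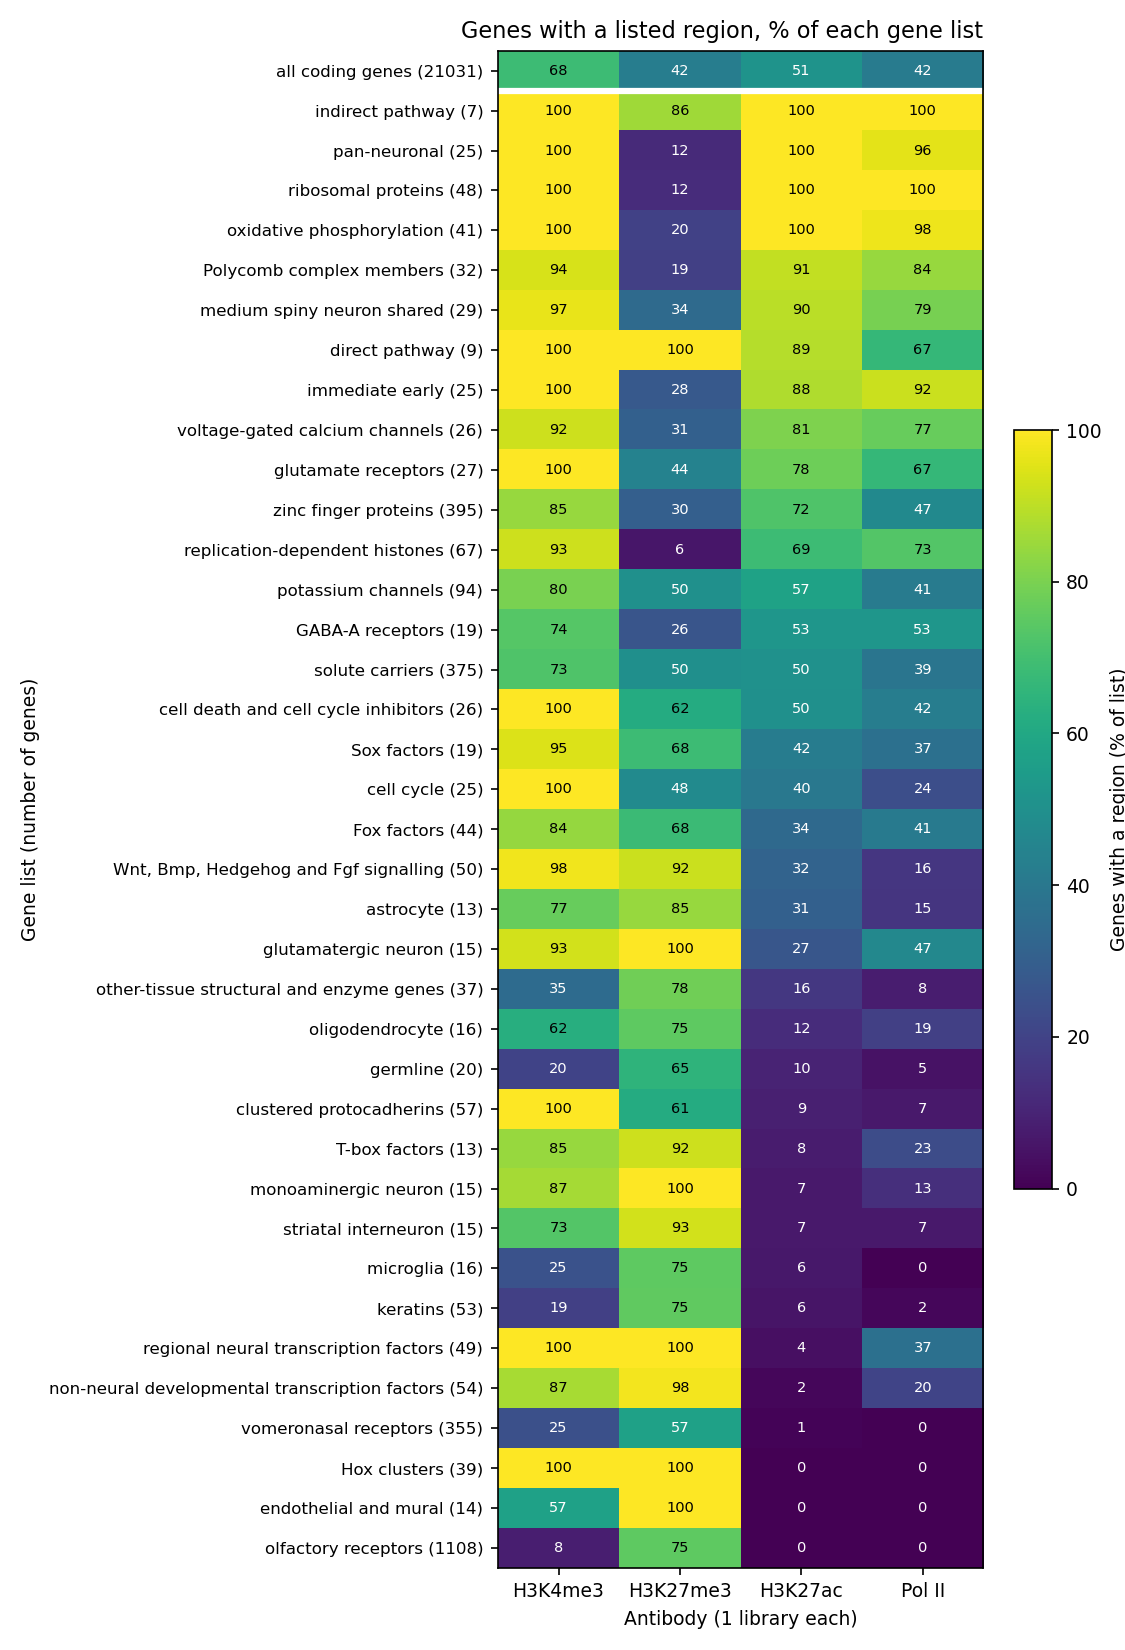
Percentage of the genes of each list (rows, number of genes in brackets) with a listed region of each antibody (columns), from 0 (dark) to 100% (yellow), with all 21031 coding genes in the top row. Lists are ordered by H3K27ac; pan-neuronal, ribosomal and medium spiny neuron genes lie near the top, Hox and olfactory receptor genes near the bottom.

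The last comparison was of region width, since wide H3K4me3 regions are a feature of cell identity genes. The median H3K4me3 width was 19.9 kb over the 28 shared medium spiny neuron genes with H3K4me3, against 6.6 kb over all 14377 genes with H3K4me3, and above all random lists of 28 genes. It was 10.9 kb for direct-pathway and 10.6 kb for indirect-pathway genes, at percentiles 99.3 and 98.3 of random lists. Glial lists were not wider than random lists, with 6.35 kb for oligodendrocyte, 6.05 kb for astrocyte and 5.1 kb for the 4 microglial genes with H3K4me3, the last at percentile 0.435. Width did not single out striatal genes: pan-neuronal genes had 10.9 kb, glutamatergic genes 13.7 kb and Hox genes 108.6 kb, where the members of a cluster share regions. The 10 widest H3K4me3 regions were those of the Hox clusters, Pde10a, Baiap2, Bcl11b and Slc6a6, the taurine transporter gene, and a pair of low-scoring regions at Sfi1 and Aadacl3. H3K4me3 regions of genes with H3K27me3 had a median of 6.0 kb against 6.9 kb without, and H3K27me3 regions of genes with H3K4me3 had 17.5 kb against 14.3 kb without.

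**Figure D4:**
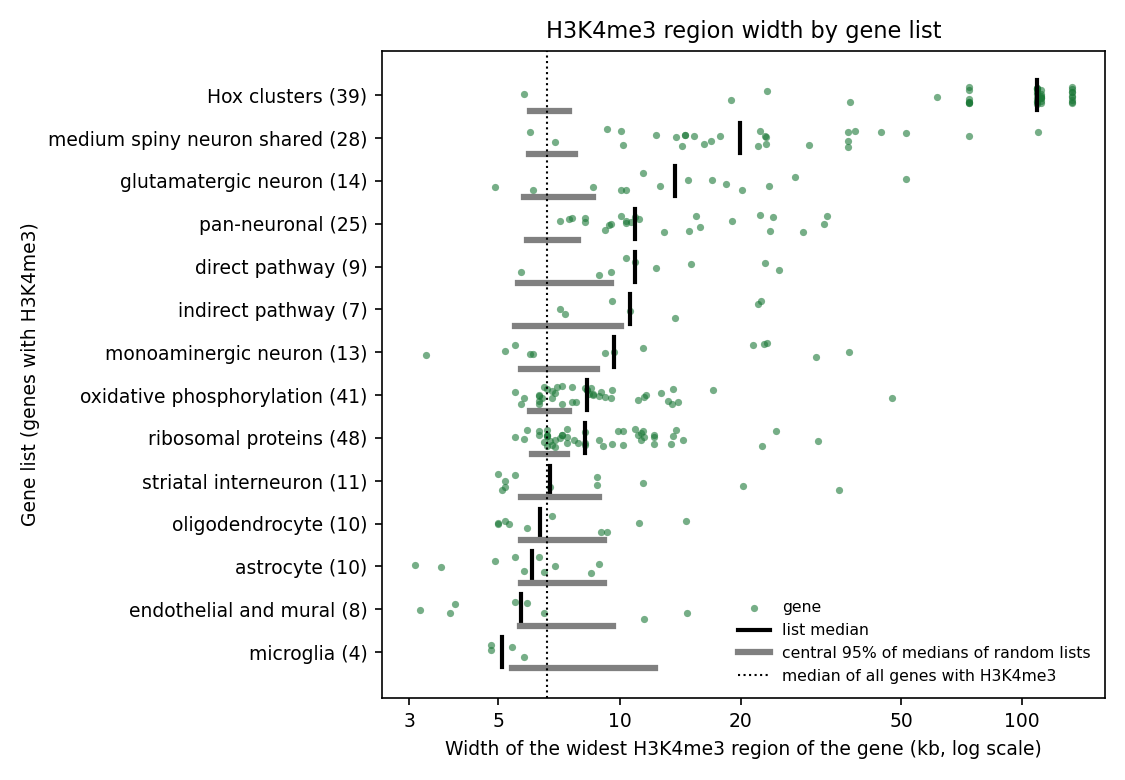
Width of the widest H3K4me3 region of each gene (points, kb, log scale) by gene list, with list medians (black bars), the central 95% of medians of random lists of the same size (grey) and the median of all genes with H3K4me3 (dotted, 6.6 kb). The median of shared medium spiny neuron genes is 19.9 kb and that of microglial genes 5.1 kb.

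Overlap was also measured by position. It covers only the listed regions near transcription start sites, so H3K27ac, H3K27me3 and Pol II away from them do not enter these shares. H3K4me3 regions covered 103 Mb, H3K27me3 205 Mb, H3K27ac 56.1 Mb and Pol II 41.9 Mb. Of the H3K27ac sequence 99.5% lay within H3K4me3 regions and 6.82% within H3K27me3 regions. Of the Pol II sequence 97.7% lay within H3K4me3 and 4.35% within H3K27me3 regions. H3K4me3 and H3K27me3 shared 25.8 Mb, or 25.2% of the H3K4me3 sequence.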

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

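Among the tests given here, those on the score of H3K27me3 and on a mixture of neuron types at pathway genes, on enrichment of every antibody at receptor genes, and the comparison of developmental factors with other genes, were chosen or extended after the result was seen. The samples differ in antibody only, and no biological explanation was tested between groups of samples.

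The region lists also reach genes outside the comparisons of coding genes. Noncoding genes and pseudogenes with a region numbered 659 for H3K4me3, 487 for H3K27me3, 447 for H3K27ac and 385 for Pol II. They stand out as signal in data that the comparisons left aside. The microRNA gene Mir124a-1, known for its neuronal expression, had the fourth highest Pol II region (8.03), and Mir9-2 scored 6.97 for Pol II and 11.7 for H3K27ac. Next among microRNA genes for Pol II came Mir124a-3, Mir207, Mir132, Mir212, Mirlet7i, Mir124a-2, Mir760 and Mir129-2. For H3K27ac the highest microRNA score was at Mir760 (12.8). Whether a region belongs to the microRNA or to a host or neighbouring gene was not tested. The H3K27ac region of Mir9-2 was also listed for C130071C03Rik. The microRNA genes with the highest H3K27me3 scores were Mir196a-2 and Mir615 (14.1), Mir10b (13.9) and Mir196b (13.8), all inside Hox clusters, followed outside the clusters by Mir182, Mir183 and Mir96 (11.4).

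Direct- and indirect-pathway genes had H3K27ac and H3K27me3 listed together at 14 of 16 genes (87.5%, 61.7 to 98.4%), among them Drd1, Drd2, Adora2a, Tac1 and Penk. H3K27me3 regions near the lowest listed scores are argued against, since their median score percentile was 78.4. The listed regions did not lie apart: at 13 of 14 genes (92.9%, 66.1 to 99.8%) they shared at least 0.5 of the narrower one, the exception being Sfxn1. Over all coding genes with both marks, regions shared that much at 621 of 2181 genes. The genes were not matched on H3K27me3 width, and a wide H3K27me3 region can contain a narrower H3K27ac region, as at Drd1 (38.7 kb and 11.4 kb). Only region bounds were compared, without a signal track, so marks on separate stretches inside a wide region stay open. The share was 59.9 points above that of shared medium spiny neuron genes (27.6%), and pan-neuronal genes had both marks at 3 of 25. A mixture of neuron types, each with 1 of the marks, cannot be told apart from both marks in the same nucleus, since either would give this difference and nuclei of both pathways were in the same libraries.

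Developmental transcription factor genes had Pol II without H3K27ac at 27 genes, such as Tal1, Tlx3, Gata2 and Tbx2. Pol II of a neighbouring gene in the same region is argued against, since 0 of the 27 regions was listed for a gene outside the lists (upper limit 12.8%). Weak regions near the lowest listed score could account for it, with a median Pol II score percentile of 12.2. All 27 regions (100%, 87.2 to 100%) lay inside H3K27me3 over at least 0.5 of their length. The share was 18.5% for 1313 other genes with H3K4me3, H3K27me3 and Pol II, but 73.1% (60.9 to 83.2%) for the 67 of them that also lack H3K27ac, so much of the contrast goes with the absence of H3K27ac. The groups were not matched on H3K27me3 width, and a wide H3K27me3 region can contain a narrow Pol II region. The highest-scoring of 10 groups of H3K27me3 genes held 93 genes of the factor lists. Its median H3K27me3 width was 67.5 kb, against 4.3 kb in the lowest-scoring group. Pol II held at H3K27me3 promoters stays open beside weak background, since either could give regions of this kind.

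Olfactory and vomeronasal receptor genes had H3K4me3 without H3K27ac or Pol II at 177 genes, 91 olfactory and 86 vomeronasal. Regions near the lowest listed score could account for most, with a median H3K4me3 score percentile of 4.22, although Olfr986 reached a score of 8.05. H3K27me3 was listed 26.6 points more often at these genes than at receptor genes without H3K4me3 (94.4% against 67.8%). Enrichment of every antibody would also raise H3K27ac and Pol II, which were listed at 2 of the 179 receptor genes with H3K4me3 (1.12%, 0.136 to 3.98%). Signal just under the lowest listed score keeps this open. Whether reads shared between near-identical receptor copies gave the 177 cannot be told apart from real H3K4me3, since neither reads nor a genome of build mm9 was used here.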

How the results depend on the processing

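Of the summary results under the alternatives, 149 stayed within the limits set and 15 moved, all of them counts. A count was compared by its size only and has no direction that could reverse. The ratios and differences all kept their direction and their call. H3K4me3 and H3K27me3 stayed below expectation in all 8 alternatives, with log2 ratios from -1.31 to -0.21, as did H3K27ac and H3K27me3, from -2.89 to -1.001. Not all of these alternatives could have changed that. Requiring shared bases can only lower the observed count against the same expected count. A background of genes with at least 1 mark can only raise the expected count. The Pol II difference between H3K4me3 genes with and without H3K27me3 ranged from -65.0 to -30.8 points and that of H3K27ac from -68.6 to -27.7 points. Leaving out olfactory and vomeronasal receptor genes, chosen after seeing the data, changed no call. In the upper 50% of each list, coding genes numbered 7774 for H3K4me3, 5265 for H3K27me3, 5492 for H3K27ac and 4450 for Pol II, by construction. Genes with H3K4me3 and H3K27me3 numbered 787, with H3K27ac and H3K27me3 276, with H3K4me3 and H3K27ac 5031 and with H3K4me3 and Pol II 3955. Lists of the same length gave 1747 genes with H3K4me3 and H3K27me3 and 1325 with H3K27ac and H3K27me3, and sharing 0.5 of the narrower region gave 621 with H3K27ac and H3K27me3. Lists above the random range for H3K4me3 were 10 in the upper 50% and 10 in lists of the same length, from 22, and lists below it were 15 and 15, from 6.

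Of the values of single gene lists, 795 kept their call, 24 moved outside the random range and 43 moved inside it. A change of sign inside the range both before and after was counted as a kept call. The other 26 changed sign and lay outside the range before or after, all in the settings that keep the highest scores. Of these, 10 lay outside the random range on opposite sides, 7 were inside it before (interneuron, monoaminergic and T-box H3K4me3 and potassium channel Pol II) and 9 were inside it after, with no call left. H3K4me3 log2 ratios, in the upper 50% and then in lists of the same length, were -4.90 and -5.12 for Hox genes, -2.41 and -1.74 for regional factors, -3.03 and -2.77 for non-neural factors, -3.41 and -3.62 for T-box factors and -0.21 and -0.16 for Fox factors. They were -3.60 and -3.81 for interneuron, -1.27 and -0.64 for glutamatergic and -2.01 and -2.23 for monoaminergic genes, and -2.62 and -2.85 for clustered protocadherins. The Fox and glutamatergic values lay inside the random range. In the upper 50% alone, the log2 ratios of H3K4me3 for cell cycle (-0.0362) and signalling genes (-0.20), of H3K27me3 for germline genes (-0.65) and of Pol II for zinc finger proteins (-0.0274) changed sign inside it. Those of H3K27me3 for vomeronasal receptor genes (-0.77) and of Pol II for potassium channels (0.58) lay outside it. H3K27ac at histone genes was -1.08, outside it, and -0.21, inside it. H3K4me3 regions of genes with H3K27me3 had a median score percentile of 28.5 against 66.3 without it, so that ranking by score removes more of them. For the other changes of sign the cause was not tested. Regions within 1 kb of the start site and a false discovery limit were not run, since neither start positions of build mm9 nor such a column was used here. No paired analysis was possible because each antibody has 1 library. Depth limits what the absence of a region shows.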

Other observations

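H3K27me3 genes were not alike across its range of scores. Ordered by H3K27me3 score into 10 groups, the share of genes that also had H3K4me3 was 39.9% (36.6 to 43.2%) in the lowest group and 90.5% (88.4 to 92.3%) in the highest. The share with H3K27ac was 27.8% in the lowest and 13.5% in the highest, and that with Pol II 16.7% and 15.0%. The median width was 4.3 kb in the lowest group and 67.5 kb in the highest. The highest group held 93 genes of the regional and non-neural factor lists and 4 olfactory and vomeronasal receptor genes, the lowest none and 190. Of the 3829 genes with H3K27me3 alone, 869 were such receptor genes.

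Chromosome X had fewer marked genes than the autosomes. H3K27me3 was listed at 197 of its 905 coding genes (21.8%), against 33.5% on chromosome 12, the lowest of the autosomes, and 49.2% on chromosome 6, the highest. H3K4me3 was listed at 52.2% of X genes. On chromosome Y, H3K4me3 was listed at Uty (7.58), Eif2s3y (6.67), Kdm5d (6.20) and Ddx3y (6.09), and also at Sry and Uba1y with scores of 2.45 and 2.01. At the start of chromosome 11, H3K4me3 (85.7 kb), H3K27ac (79.2 kb) and H3K27me3 (66.5 kb) each had a wide region over Pisd-ps1 and Pisd-ps3 with scores of 2.20, 2.58 and 2.31, and Pol II had none. These regions were singled out after their values were seen.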
